A study of Mus musculus with 4 samples.

How the data were processed

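RNA was measured in the cerebral cortex of newborn C57BL/6J mice on postnatal day 1 in 4 libraries, 2 labelled Control (replicates 2 and 3, both alleles of Mkk7 floxed) and 2 labelled cKO (replicates 2 and 3, the same alleles with Emx1-Cre). Per the labels' protocols, TRIzol-extracted total RNA was treated with DNase and made into libraries with SMART-Seq v4, a low-input kit that primes on poly(A) tails and does not mark the strand. The deposited table holds estimated counts per gene and transcripts scaled to a fixed total (TPM) for each library. The authors' TPM columns each summed to 1e+06. The authors used DRAGEN and genome build GRCm39, per the submitters' processing notes; the version, the annotation release, the settings and any filter are not given in the sources used here. Between 12.0% and 13.5% of all 55414 rows held an estimated count that was not whole in a library. Only 21598 to 21914 rows had counts in a library, so the share among genes with counts is higher. Reads that match several genes can thus have been split between them. Values of pseudogenes and near-identical copies are therefore uncertain, as are those of genes that overlap on opposite strands. The deposited gene length, 1 value per gene, entered only the estimate of apparent transcript length. Gene names and coordinates are those of the deposited table, and no coordinate of another build was used.

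The deposited estimated counts were rounded to whole numbers. Library totals were 19429868, 19842152, 19421470 and 22511175 counts for Control 2, Control 3, cKO 2 and cKO 3. All 55414 rows named a gene. Genes were kept by the default filter of edgeR (version 4.0.16, R 4.3.3), which left 17017. Libraries were scaled with TMM factors (1.01, 0.994, 0.979 and 1.02), and genotypes were compared with edgeR's quasi-likelihood test without robust shrinkage, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were the absolute log2 fold change divided by the square root of the F statistic. Levels are counts scaled to a library of 1e+06 (CPM), with the SD over the 2 libraries of a group. The labels do not say whether the libraries of a group came from separate animals or litters, so p-values measure only the spread between these libraries, which can be partly technical. The libraries were not duplicates of each other: the chi-square of counts per degree of freedom was 13.3 between both Control libraries and 29.7 between both cKO libraries. Replicate numbers are shared between groups, but the labels do not tie a number to a litter, batch or day, so the genotype was the only term of the model.

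The test was checked on simulated counts for the same 17017 genes, with 200 genes changed. It recovered 66 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, each in the right direction. There were 14 false calls among 16817 unchanged genes. Changed genes had a mean of at least 5 CPM and counts were drawn at the fitted dispersions. These shares therefore check the procedure and do not measure its power on the real libraries. For lists, a simulated list of 30 genes raised 1.5-fold was called by camera with a preset correlation. Its camera adjusted p was 0.289 with an estimated correlation. None of the 45 simulated unchanged lists was called, but the simulated genes varied independently. Real lists had estimated correlations of up to 0.856 (cytosolic ribosomal proteins), and 0.439 for striatal neurons. The simulation therefore does not give the rate of false list calls in these libraries.

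Before the data were examined, 46 gene lists (pathways, cell types and technical sets) with 1307 different genes were fixed. Of these genes, 1297 matched a symbol of the table, 8 matched through RefSeq synonyms (GRCm38.p6 names only) and 2 did not match. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 46 lists. The correlation estimated by camera and fry were run beside it. The genes named in the text follow a rule fixed at the same time: Map2k7, Map2k4, Mapk8, Mapk9 and Mapk10; in each direction up to 10 genes with the largest fold change among those past the threshold with a mean CPM of at least 5, no overlap between groups and no predicted symbol, or, with fewer than 5 of these, the 5 with the smallest p; and up to 4 members with the smallest p of each list. Genes named outside the rule are marked as such, and 1 gene that the rule names is not reported here.

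The alternatives were RLE and upper-quartile scaling, no filter, a mean CPM of at least 1, DESeq2 (version 1.42.0), limma-voom, robust shrinkage, a replicate block, leaving out each library, a minimum log2 fold change of 1 and protein-coding genes only. Alternatives added after seeing the data left out chromosomes X and Y, left out pseudogenes and predicted genes, used a threshold of 0.1, or used only genes held by 1 list. A pseudocount was not varied because counts were at hand. TPM values are not counts and no call rests on them; they served as a side check of list medians and for the apparent transcript length. The 3 second lists of the closing section were first tested, in error, on rounded TPM values put through the count model, before the test on counts; the lists and their bounds were the same in both, and the medians of both are given. Intervals pool the counts of the 2 libraries of a group, so they cover counting error only and not the spread between libraries. The reads carry no molecular identifiers, so copies of 1 molecule could not be told apart and the intervals can be too narrow.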

Results

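The series compared the cerebral cortex of newborn mice with and without Emx1-Cre on a background of floxed Mkk7 alleles, to ask what the kinase MKK7 does in the developing cortex. MKK7, encoded by Map2k7, phosphorylates the JNK kinases, and Emx1-Cre recombines in the progenitors of the dorsal telencephalon and in the excitatory neurons and glia they produce. There were 2 libraries labelled Control and 2 labelled cKO, with totals between 19421470 and 22511175 counts and counts in 21598 to 21914 genes. Xist was read 1145, 1004 and 1218 times in Control 2, Control 3 and cKO 2. In cKO 3 Xist had 0 counts and the Y-linked gene Ddx3y 985, against 0 in the other libraries, so cKO 3 came from a male and the other 3 libraries from females.

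Map2k7 RNA was not lower in the libraries labelled cKO. Map2k7 (ENSMUSG00000002948.20; chromosome 8, 4288740 to 4297897, GRCm39) stood at 38.4 and 30.4 CPM in Control 2 and Control 3 and at 47.9 and 48.2 CPM in cKO 2 and cKO 3. The log2 fold change was 0.48 (SE 0.18, n = 2 per group; edgeR adjusted p = 0.428), so the gene did not pass the threshold. The direction goes against the label, but the values are sums over the whole gene. The labels do not say which exons were floxed, and reads outside a deleted part check nothing, so the labels of these libraries could not be checked from this gene. Each direction given for the libraries labelled cKO rests on those labels alone. The other kinases of the pathway named in advance also stayed short of the threshold. Map2k4, which encodes the second JNK-activating kinase MKK4, had a log2 fold change of -0.10 (SE 0.22). The JNK genes Mapk8, Mapk9 and Mapk10 had values of 0.15 (SE 0.16), 0.04 (SE 0.13) and -0.03 (SE 0.13), with edgeR adjusted p-values between 0.778 and 0.965. The sign of these small values was not stable: Map2k4 was at 0.186 without cKO 2 and at -0.465 without cKO 3, Mapk9 at -0.0100 without cKO 3, and Mapk10 at 0.0667 without Control 2, 0.0584 without cKO 2 and 0.0122 with upper-quartile scaling.

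Of the 33 tested members of the JNK pathway list, none passed the threshold over all genes or adjusted over the list alone. The list did not pass against other genes (camera adjusted p = 0.738), and 16 members had a positive and 17 a negative fold change. The member with the smallest p was Map3k12, which encodes the JNK-activating kinase DLK, at 82.5 and 101 CPM in the libraries labelled Control and 52.7 and 66.0 CPM in those labelled cKO (log2 fold change -0.63, SE 0.18, edgeR adjusted p = 0.339). None of the 18 tested JNK substrates and AP-1 factors passed either test (camera adjusted p = 0.423). Atf2, a transcription factor that JNK phosphorylates, had the smallest p of that list (log2 fold change 0.44, SE 0.19). The axon injury response list, of genes induced after axon injury, many of them through DLK and JNK, held members that moved both ways and did not pass as a whole (camera adjusted p = 0.944 over 20 tested members, 9 positive and 11 negative). None passed over all genes; adjusted over the list alone 3 rose and 2 fell. Those that rose were Sox11 (log2 fold change 0.71, SE 0.12), Flrt3 (0.58, SE 0.12) and Hspb1 (1.11, SE 0.32), and those that fell were Ecel1 (-1.55, SE 0.23), which the striatal list also holds, and Chac1 (-0.95, SE 0.28), named after its values were seen. For the 37 tested genes of the microtubule and axon cytoskeleton the camera adjusted p was 0.732, and Dcx, which encodes a microtubule-binding protein of migrating neurons, had a log2 fold change of 0.26 (SE 0.09). Axon guidance genes had a camera adjusted p of 0.165 over 45 tested members. Adjusted over the list alone, 1 of them fell: Ntn1, which encodes the guidance cue netrin-1, at 15.2 and 15.9 CPM in the libraries labelled Control and 4.79 and 3.42 CPM in those labelled cKO (log2 fold change -1.92, SE 0.31). The axon guidance list passed the threshold when cKO 2 was left out (adjusted p = 0.00162).

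Over all 17017 tested genes, 1 was higher and 7 were lower in the libraries labelled cKO (edgeR adjusted p below the threshold of 0.05). At an unadjusted p below 0.05 there were 898 higher and 964 lower genes, against 851 in all by chance. The libraries of the 2 groups did not overlap for 44.1% of the genes, where chance gives 33.3%. The gene that rose was Hspa5, which encodes BiP, the main chaperone of the endoplasmic reticulum (ER). Hspa5 (chromosome 2, 34661982 to 34667559) went from 296 ± 17.8 CPM to 705 ± 89.5 CPM (SD, n = 2), a fold of 2.39 (log2 fold change 1.25, SE 0.12, edgeR adjusted p = 0.0414). The next 4 by p did not pass. Xbp1, a transcription factor of the unfolded protein response, stood at 129 ± 3.42 and 272 ± 24.5 CPM (log2 fold change 1.08, SE 0.12, edgeR adjusted p = 0.0671). Calr, which encodes the ER chaperone calreticulin, stood at 310 ± 28.6 and 579 ± 0.68 CPM (log2 fold change 0.90, SE 0.11, edgeR adjusted p = 0.0942). The somatostatin receptor gene Sstr2 and the arrestin-domain gene Arrdc4 had log2 fold changes of 0.91 (SE 0.13) and 1.10 (SE 0.16), both with an edgeR adjusted p of 0.18.

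Among the genes that fell were 3 genes of retinoid signalling and of the centromere. Rxrg, which encodes the retinoid X receptor gamma, fell from 75.4 ± 16.8 to 5.60 ± 3.16 CPM (SD, n = 2; log2 fold change -3.73, SE 0.38). Crabp1, which encodes a retinoic acid-binding protein, fell from 53.1 ± 12.9 to 9.28 ± 1.80 CPM (log2 fold change -2.51, SE 0.26). Hjurp, which encodes the chaperone of the centromeric histone CENP-A, fell from 55.9 ± 5.59 to 14.8 ± 1.83 CPM (log2 fold change -1.92, SE 0.20). The edgeR adjusted p was 0.0414 for each. Of the remaining 4, 3 carry the names of copies of other genes, whose reads can be split with their relatives, and 1 is a predicted gene. Rpl15-ps6, a processed pseudogene of a ribosomal protein gene (chromosome 15, 52341013 to 52341624), fell from 52.3 ± 1.45 to 0.838 ± 0.379 CPM (log2 fold change -5.98, SE 0.33, edgeR adjusted p = 0.00355). Rpl15-ps2 (chromosome 9, 71968219 to 71968831) had 462 counts in the libraries labelled Control and 4 in those labelled cKO, a ratio of 0.00814 after scaling (95% exact binomial interval 0.00221 to 0.0210; edgeR adjusted p = 0.0101). Lamtor3-ps (chromosome 14, 16057291 to 16063946) fell from 64.2 ± 4.46 to 8.66 ± 2.34 CPM (log2 fold change -2.89, SE 0.24, edgeR adjusted p = 0.0176). The predicted gene Gm3373 (chromosome 14, 16728196 to 16751437), named outside the rule after its values were seen, fell from 24.2 and 26.7 to 1.42 and 1.14 CPM (log2 fold change -4.31, SE 0.30, edgeR adjusted p = 0.0101).

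**Figure D1:**
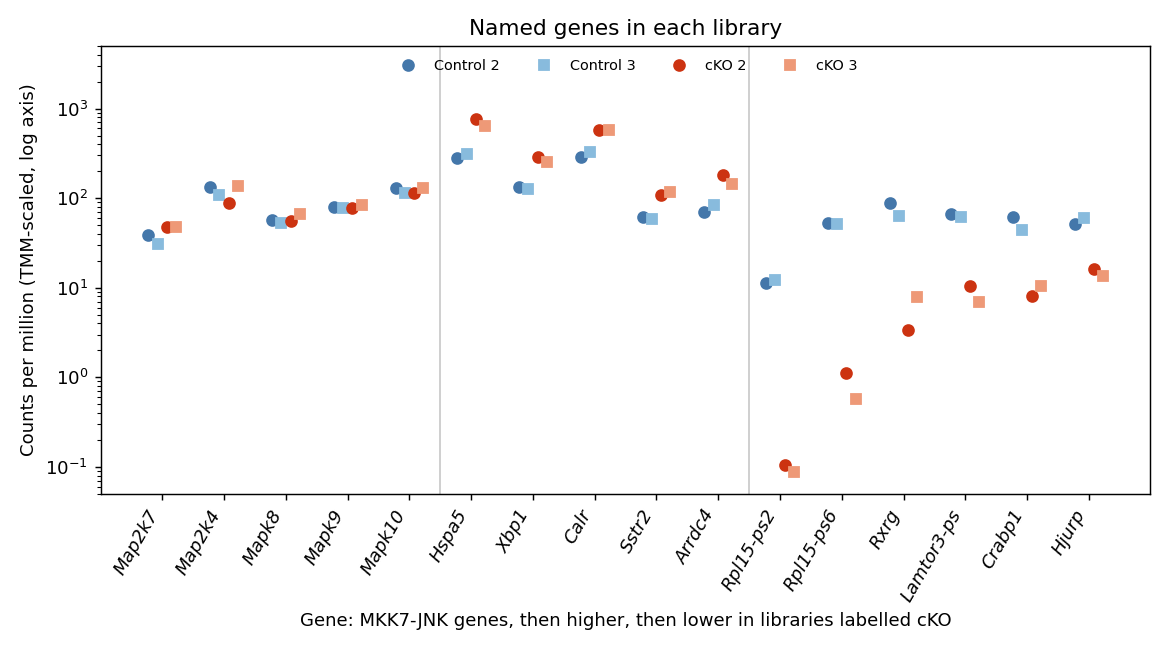
CPM (TMM-scaled, log axis) of the genes named by the rule, 1 point per library, with circles for replicate 2 and squares for replicate 3; vertical lines part the MKK7 and JNK genes, the genes with higher and those with lower values in the libraries labelled cKO. Map2k7 sits at 47.9 and 48.2 CPM in the libraries labelled cKO and at 38.4 and 30.4 CPM in those labelled Control, and Rpl15-ps2 at about 0.1 CPM in both libraries labelled cKO.

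**Figure D2:**
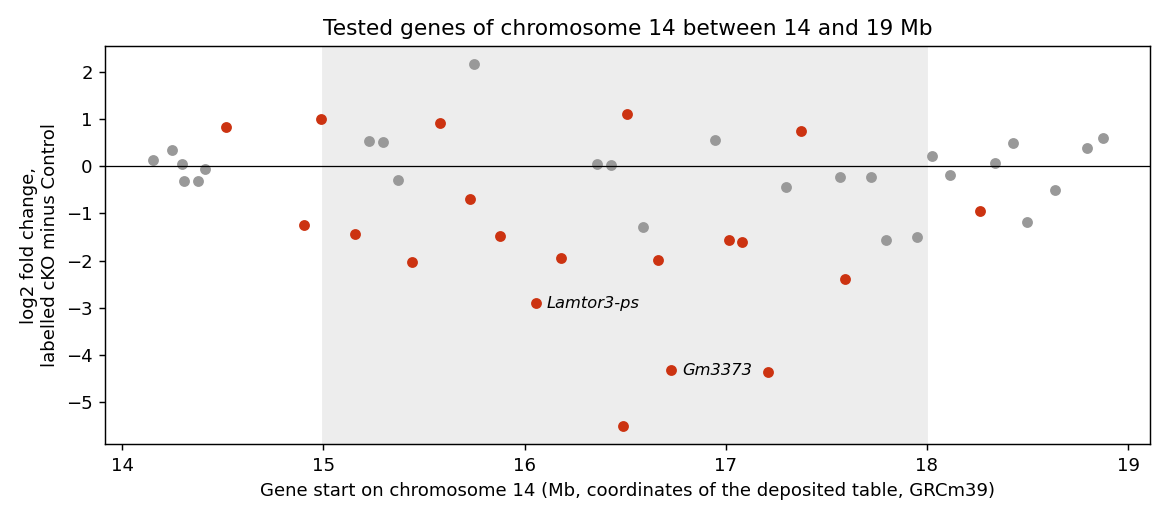
Log2 fold changes (labelled cKO minus labelled Control, 2 libraries each) of the tested genes of chromosome 14 by gene start in Mb, with red points for an unadjusted p below 0.05 and grey for the rest. In the shaded interval from 15 to 18 Mb, chosen after the values were seen and holding 28 predicted genes, 13 of 29 genes were lower at that p, among them Lamtor3-ps (-2.89) and Gm3373 (-4.31).

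These 8 calls rest on all 4 libraries. Leaving out Control 2, Control 3, cKO 2 or cKO 3 ended every call except that of Rpl15-ps6 without cKO 2 (edgeR adjusted p = 0.0447, and 0.151 to 0.918 for the other calls); the fold changes kept their sign, and that of Hspa5 lay between 1.12 and 1.38. DESeq2 called 80 higher and 105 lower genes, which included all 8.

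Genes of striatal neurons were lower in the libraries labelled cKO as a group. All 21 tested members of the striatal list had a negative fold change, with a median log2 fold change of -1.55 (camera adjusted p = 1.3e-28; adjusted p = 0.762 with an estimated correlation). None passed the threshold over all genes, and 14 fell when adjusted over the list alone. The retinoic acid receptor gene Rarb went from 18.3 ± 4.10 to 3.05 ± 1.28 CPM (SD, n = 2; log2 fold change -2.59, SE 0.38). Ecel1 and the transcription factor gene Ebf1 had log2 fold changes of -1.55 (SE 0.23) and -2.09 (SE 0.33). Genes of the olfactory bulb and rostral stream were also lower, with 11 of 14 negative and a median of -0.41 (camera adjusted p = 0.00580; adjusted p = 0.800 with an estimated correlation). Adjusted over that list alone 1 fell, Pbx3 (log2 fold change -1.51, SE 0.27). Of 30 cortical interneuron genes 19 were negative, with a median of -0.18 (camera adjusted p = 0.0131; adjusted p = 0.762 with an estimated correlation). Adjusted over the list alone 1 of these fell, the somatostatin gene Sst, from 223 and 203 CPM to 143 and 126 CPM (log2 fold change -0.67, SE 0.13). Gad2, which encodes a GABA-synthesizing enzyme, had a log2 fold change of -0.60 (SE 0.17). The olfactory and interneuron calls were lost without Control 2 (adjusted p = 0.118 and 0.128) and without cKO 3 (adjusted p = 0.0601 and 0.292), and the interneuron call also over genes held by no other list (adjusted p = 0.0851, an alternative chosen after seeing the data). The striatal call was kept without each library.

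The list of the integrated stress response held both genes that rose and genes that fell. Over all genes 1 of its 34 tested members passed, Hspa5. Adjusted over the list alone 11 rose and 4 fell, and the list as a whole was higher (camera adjusted p = 8.91e-05; adjusted p = 0.762 with an estimated correlation), with a median of 0.07 and a mean of 0.22. Most of those that rose act in protein folding in the ER or regulate it: besides Hspa5, Xbp1 and Calr they included the protein disulfide isomerase gene Pdia4, at 78.1 and 72.9 CPM in the libraries labelled Control and 135 and 128 CPM in those labelled cKO (log2 fold change 0.80, SE 0.13). The 4 that fell, named here after their values were seen, were Asns (-0.61, SE 0.12), Mthfd2 (-0.84, SE 0.19), Chac1 (-0.95, SE 0.28) and Slc7a5 (-0.45, SE 0.14), genes of amino acid and one-carbon metabolism and transport and of glutathione breakdown. The list's call was lost without Control 2 (adjusted p = 0.102) and without cKO 2 (adjusted p = 0.0537). In the same libraries the meningeal and fibroblast list had a median of 0.44 and the striatal list one of -1.55. The transcripts of the mitochondrial genome were positive in 13 of 13 cases (median 0.17). A list of 12 genes with transcripts held in the nucleus at least in part, chosen after seeing the data, had a median of -0.41. Of these 9 were negative, among them Rsrp1 (-1.01) and Snhg11 (-1.26).

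Genes of the meninges and fibroblasts were higher in the libraries labelled cKO, with 31 of 36 positive and a median of 0.44 (camera adjusted p = 2.82e-06; adjusted p = 0.762 with an estimated correlation). None passed adjusted over the list alone. The collagen gene Col5a2 and the proteoglycan gene Dcn had log2 fold changes of 0.92 (SE 0.26) and 0.67 (SE 0.20). Intermediate progenitor genes were higher as well, with 15 of 18 positive and a median of 0.28 (camera adjusted p = 0.000484; adjusted p = 0.762 with an estimated correlation). Sstr2 and Sox11, a transcription factor gene of young neurons, rose adjusted over that list alone; Sox11 went from 465 and 377 CPM to 680 and 697 CPM (log2 fold change 0.71, SE 0.12). The neurogenic factor genes Insm1 and Neurog2 had values of 0.60 (SE 0.18) and 0.75 (SE 0.27). Astrocyte genes were lower, with 25 of 29 negative and a median of -0.18 (camera adjusted p = 0.00159; adjusted p = 0.762 with an estimated correlation). Adjusted over the list alone the apolipoprotein gene Apoe fell, from 664 and 738 CPM to 490 and 479 CPM (log2 fold change -0.53, SE 0.10). The water channel gene Aqp4 had a value of -0.79 (SE 0.24). These 3 calls were kept without each library; that of the intermediate progenitors was lost over genes held by no other list (adjusted p = 0.0684).

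Among the other lists past the threshold, Wnt pathway genes were higher, with 27 of 35 positive and a median of 0.21 (camera adjusted p = 0.0131; adjusted p = 0.803 with an estimated correlation). None passed adjusted over the list alone; Rnf43 had the smallest p, at 1.48 and 0.914 CPM in the libraries labelled Control and 0 counts in those labelled cKO, and Sfrp1 and Wnt7b had log2 fold changes of 0.54 (SE 0.14) and 0.46 (SE 0.13). This call was lost without cKO 3 (adjusted p = 0.325). Transcripts of the mitochondrial genome had positive values in 13 of 13 cases with a median of 0.17 (camera adjusted p = 0.000484; adjusted p = 0.762 with an estimated correlation), and mt-Atp8 rose adjusted over the list alone (log2 fold change 0.75, SE 0.15). All genes of the mitochondrial chromosome, those outside the list included, made up 1.14%, 1.14%, 1.20% and 1.29% of the counts of Control 2, Control 3, cKO 2 and cKO 3. Replication-dependent histone genes were higher, with 13 of 17 positive and a median of 0.37 (camera adjusted p = 0.0233, or 0.803 with an estimated correlation). H1f2 and H2bc4 rose adjusted over the list alone, by 1.13 (SE 0.24) and 0.91 (SE 0.20) on the log2 scale. Most transcripts of these genes lack the poly(A) tails that the kit primes on, and only 17 of the 41 listed were tested. The list was a technical set, and its values need not follow histone expression. The histone call was lost without Control 2, Control 3 or cKO 2 (adjusted p = 0.0566, 0.0596 and 0.521) and on voom values (adjusted p = 0.0610). Cytosolic ribosomal protein genes were lower, with 51 of 56 negative and a median of -0.16 (camera adjusted p = 0.000225; adjusted p = 0.861 with an estimated correlation), and none passed adjusted over the list alone. Without cKO 3 the direction of that list turned and the call was lost (adjusted p = 0.325); its median log2 deviation from the mean of the libraries was -0.33 in cKO 3 and 0.07, 0.12 and 0.12 in Control 2, Control 3 and cKO 2.

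**Figure D3:**
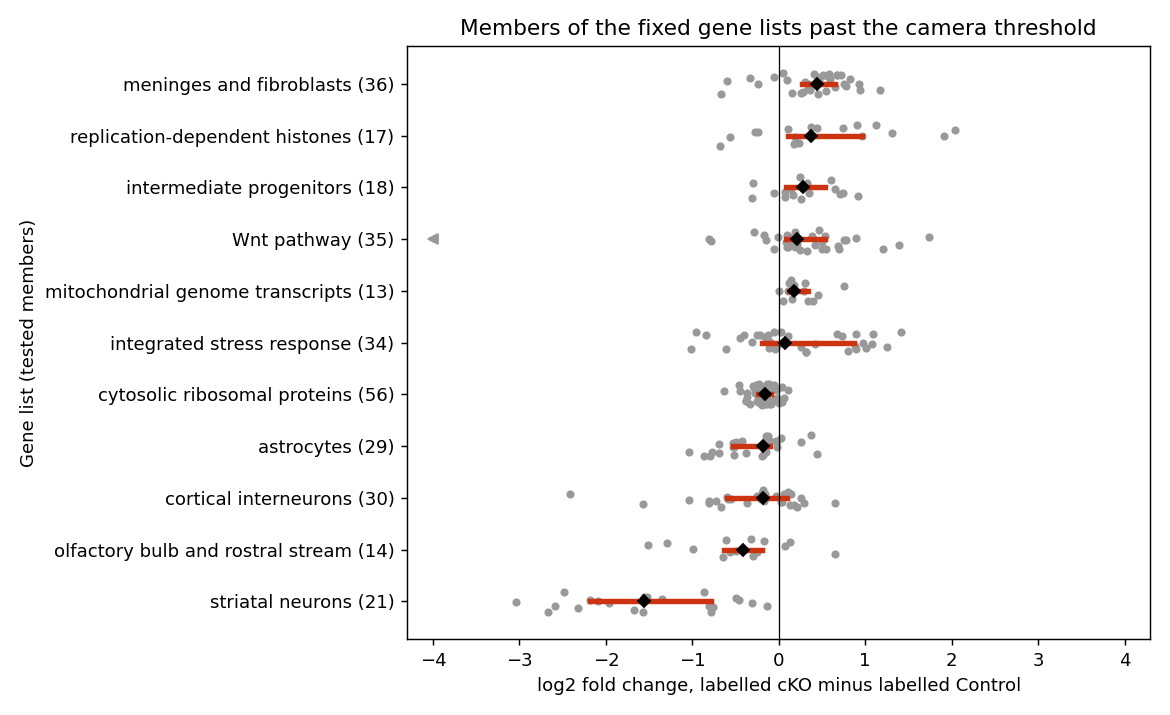
Log2 fold changes (labelled cKO minus labelled Control, 2 libraries each) of the tested members of the 11 fixed lists past the camera threshold, with grey points for genes, red bars for the quartiles, black diamonds for the medians and a triangle for the 1 gene beyond the axis. The medians run from -1.55 for striatal neurons to 0.44 for meninges and fibroblasts.

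The 35 other lists did not pass (camera adjusted p from 0.0770 to 0.944), and in 11 of them members passed adjusted over the list alone. Several of these lists passed in an alternative. Choroid plexus and ependyma genes were lower without Control 3 (adjusted p = 0.000131) and without cKO 2 (adjusted p = 0.00158), and oxidative phosphorylation genes were lower on voom values (adjusted p = 0.00986) and without cKO 2 (adjusted p = 1.24e-10). Red blood cell genes were lower without cKO 2 (adjusted p = 2.36e-05) and higher without cKO 3 (adjusted p = 0.0282). Higher were cholesterol synthesis without Control 2 (adjusted p = 0.0101), cell adhesion and extracellular matrix of neurons without cKO 2 (adjusted p = 0.00342), heat shock without cKO 3 (adjusted p = 0.0307) and hypoxia and glycolysis at a mean CPM of at least 1 (adjusted p = 0.0172). Deep-layer neuron genes had a median log2 fold change of 0.13 (camera adjusted p = 0.416 over 35 members) and upper-layer neuron genes stayed short of the threshold (adjusted p = 0.0799 over 27 members); the upper-layer list passed without Control 3 (adjusted p = 0.00342) and without cKO 2 (adjusted p = 0.0153), and over genes held by no other list (adjusted p = 0.0407). Foxp1, a transcription factor gene of deep-layer and striatal neurons, had a log2 fold change of -0.49 (SE 0.12), and Ptprk one of 0.48 (SE 0.14). Radial glia (28 tested genes) and the cell cycle (48 tested genes) had camera adjusted p-values of 0.632 and 0.738, with Ttyh1 at -0.43 (SE 0.13) and Mcm5 at -0.65 (SE 0.17). No member of these 4 lists passed adjusted over its list alone. With an estimated correlation no list of the 46 passed; 1 list had an unadjusted p below 0.05. By fry, 0 lists moved one way at an adjusted p below 0.05 (5 at an unadjusted p below 0.05), and 19 held changes in either direction.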

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

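The alternatives that left out chromosomes X and Y, left out pseudogenes and predicted genes, used a threshold of 0.1 or used only genes held by 1 list were chosen after seeing the data. Counts of genes higher and lower in the libraries labelled cKO were the most dependent on the tool and filter: against 1 and 7, there were 21 and 37 with no filter and 80 and 105 with DESeq2, and each of these sets held all 8 genes. Higher genes numbered 2 at a mean CPM of at least 1, 3 with limma-voom (6 of the 8 genes shared), 3 with protein-coding genes only and 3 at a threshold of 0.1; without pseudogenes and predicted genes there were 3 higher and 3 lower. RLE and upper-quartile scaling, robust shrinkage, a minimum log2 fold change of 1 and leaving out chromosomes X and Y kept the same 8 genes. The cause was not tested except where fewer genes or libraries entered by construction. Without 1 library, the groups have 1 and 2 libraries and the lone library is assumed to vary like the others: higher genes numbered 0 in each case and lower genes 0 to 2 by edgeR, with 880 to 2335 genes at an unadjusted p below 0.05. Map2k7 kept its positive sign in every alternative, from 0.32 to 0.66 without 1 library. Against 6 lists higher and 5 lower, an estimated correlation left 0 and 0; without 1 library lists higher numbered 5 to 7 and lists lower 2 to 8. Over 185 other named genes, 2118 of 2211 values stayed on their side of the threshold, 50 passed it, 30 no longer did and 13 turned sign, none of a called gene. Those were Mapk10 with upper-quartile scaling (0.0122), the hemoglobin genes Hbb-bt (-0.0268) and Hbb-bs (-0.124) with limma-voom, and, without 1 library, Map2k4 (-0.465 to 0.186), Mapk9 (-0.0100 to 0.0859), Mapk10 (-0.120 to 0.0667), Sostdc1 (-1.17 to 0.112), Zic4 (-1.30 to 0.224), Hbb-bt (-0.715 to 0.713) and Hbb-bs (-0.910 to 0.725). The libraries share only a replicate number: deviations of same-numbered libraries had a correlation of 0.0136 across genes, and with a replicate block there were 1 higher and 6 lower genes (without Hjurp), 7 lists higher and 7 lower (all 11 and upper-layer neurons, higher, adjusted p = 0.0420, choroid plexus and oxidative phosphorylation, lower, adjusted p = 0.0205 and 0.0340), a Map2k7 value of 0.49 and an Hbb-bs value of -0.0890. With 2 libraries a group, the simulated test missed 34 of 100 genes changed 2-fold. The real libraries also held larger changes that stayed short of the threshold, such as Rarb (log2 fold change -2.59, edgeR adjusted p = 0.18). The simulated shares therefore do not bound the size of a change that could be missed.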

Other observations

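Of the tests in this part, only that on the second striatal list was fixed before its values were seen; all others were chosen after results were seen, including those on the ER folding and amino acid lists, since annotation terms that share genes with them had already been seen to move the same way. Emx1, the gene whose promoter drives Cre, stood at 12.6 and 11.1 CPM in the libraries labelled Control and 22.5 and 17.2 CPM in those labelled cKO (log2 fold change 0.75, SE 0.25, edgeR adjusted p = 0.399). Genes with transcripts held in the nucleus at least in part were lower, with 9 of 12 negative and a median log2 fold change of -0.41 (camera p = 2.18e-06, or 0.158 with an estimated correlation). Some of the 12, such as Clk1, Clk4 and Rsrp1, also have transcripts outside the nucleus. Meg3 had -0.88 and Snhg11 -1.26. Map2k7 reads per TPM gave apparent transcript lengths of 3444 and 3787 bases in the libraries labelled Control and 4009 and 3961 bases in those labelled cKO; a log2 difference of 0.14 or more was seen in 16.3% of 8386 genes with several transcripts. By the table's own annotation terms, 2 of 691 molecular function terms passed camera, protein disulfide isomerase activity and misfolded protein binding, both higher (camera adjusted p = 0.00556 and 0.0441; p = 0.0619 and 0.0935 with an estimated correlation); 0 of 2440 biological process and 0 of 512 cellular component terms passed. Of 1024 Reactome terms 7 passed: 3 of MET signalling and 2 of the extracellular matrix were higher (p from 0.0359 to 0.0744 with an estimated correlation), as was the meningeal list, and nonsense-mediated decay and SRP-dependent targeting were lower (p = 0.590 and 0.603 with an estimated correlation). The hypothesis was that amino acid and tRNA synthetase genes were lower as a class, opposite to the ER genes of the same stress list. It was tested on 17 genes outside that list, of which 13 were negative, with a median of -0.334. The camera p was 5.03e-06, or 0.160 with an estimated correlation, and the median of TPM ratios was -0.42. The earlier fit to TPM values gave -0.458 over 15 genes.

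Lower striatal markers may come from less striatal tissue in the libraries labelled cKO, for example by a different dissection, or from a biological difference of the genotype, which was not tested. A second list of 23 striatal genes had a median of -0.280 with 17 negative (camera p = 0.00369; p = 0.125 with an estimated correlation; median of TPM ratios -0.16), and the earlier fit to TPM values had given -0.0298 over the 9 genes it kept. The count value lay between the bounds set in advance, -0.5 for less striatal tissue and -0.2 against it, while both TPM values lay past the bound against it, so the test left the tissue share open; the most abundant of these genes, Sez6, stood at 412 and 460 CPM in the libraries labelled Control and 424 and 553 CPM in those labelled cKO. For the first striatal list only, the tables argue against fewer GABAergic neurons of every kind as the whole cause. The 29 interneuron genes outside the striatal list had a median of -0.183, against -1.55 for the striatal list. Quartiles were -0.598 and 0.0972 over all 30 interneuron genes, and -2.19 and -0.785 for the striatal list. The second striatal list, with a median of -0.280 and quartiles of -0.832 and 0.0431, lay near the interneuron genes and was not tested against them. It does not part the 2 kinds of neuron. The permutation p of 4e-05 over genes, which are not independent, is too small, because the striatal list was singled out by its low values. How the cortex was dissected is not given in the sources used here.

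Higher ER genes of the stress list were weighed against tissue shares and sex. These 11 genes, mostly of chaperones but with the transcription factor gene Xbp1 among them, had a median of 0.90 (quartiles 0.764 and 1.08). They were parted from the rest of that list after its values were seen. They are not the same 11 that rose adjusted over the list alone, since Herpud1 was at -0.12 and Dnajb9 at 0.10. Another 34 ER folding genes outside it, also chosen after related terms were seen, had a median of 0.247. This lay below the 0.442 of 36 meningeal genes (permutation p = 0.00299 over genes), so more meningeal tissue stays open for the 34 genes. The meningeal quartiles, 0.269 and 0.652, lay below those of the 11 genes. That argues against more meningeal tissue as the whole source for the 11, though they were picked after values were seen. The median of the 34 genes lay above the 0.134 of 62 upper- and deep-layer genes (permutation p = 0.0167 over genes). Less striatal tissue alone would raise layer genes that the striatum lacks at least as far as the ER genes. Both ER sets rose further, and the lower quartile of the 11 genes was 0.764. For those 11 genes this argues against less striatal tissue as the whole source. It is not excluded, since both ER sets were chosen after rises were seen. The layer genes also include Foxp1, a gene of striatal neurons too. The tables argue against the male library as the whole source: in the female cKO 2 the median log2 ratio of the 11 genes to the Control mean was 1.01, with 10 of 11 above both Control libraries. A rise of ER folding genes as a class was tested on the 34 genes, of which 31 were positive (camera p = 8.35e-07; p = 0.0296 with an estimated correlation; median of TPM ratios 0.21); the median is just past the bound of 0.2, which the earlier fit to TPM values, seen first, had missed (0.195 over 28 genes, camera p = 3.84e-05), with the same direction in all 3. A response of the cortex in the libraries labelled cKO is one hypothesis. Handling of the tissue, RNA quality or a litter difference stays open. In the same libraries the list of partly nuclear transcripts had a median of -0.41, and the mitochondrial transcripts were positive in 13 of 13 cases.

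In the libraries labelled cKO, 2 copies of Rpl15 (Rpl15-ps2 and Rpl15-ps6) were near absent and Lamtor3-ps was low, at 10.3 and 7.01 CPM, while Rpl15-ps3 stood at 188 and 113 CPM against 92.6 and 99.2 CPM in those labelled Control (edgeR adjusted p = 0.406). Reads moved between Lamtor3 and its copy would leave their sum the same, but it went from 130 and 121 CPM to 69.3 and 67.7 CPM (log2 ratio -0.876), with Lamtor3 itself at 62.9 and 60.3 against 59.0 and 60.7 CPM. For Rpl15 and its 6 named copies the sum was 489 and 504 against 524 and 385 CPM (log2 ratio -0.128); reads simply gone would give -0.20 and the SD within groups was 0.22, so moved and lost reads cannot be told apart. Around Lamtor3-ps, 13 of 29 tested genes of chromosome 14 from 15 to 18 Mb were lower at an unadjusted p below 0.05 and 3 higher, with a summed CPM of 303 and 290 against 167 and 138; the interval was drawn around genes seen to be low, and 28 of the 29 are predicted genes, between which reads can be split, so their number tests nothing. A copy number or sequence difference between the founder mice is a candidate explanation that cannot be told apart from the genotype, since no sequence was analysed here; no biological explanation was tested.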
